A study of Homo sapiens with 10 samples.

How the data were processed

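The study profiled m6A, the methyl mark on adenosines in RNA, by MeRIP-seq, in which fragmented RNA is pulled down with an antibody against the mark and sequenced beside an input that was not pulled down. The cells were V16A, a line of castration-resistant prostate cancer. Of 10 samples, 5 were pulled down and 5 were inputs. The pulled-down samples were 2 of hypoxia, 2 of normoxia and 1 named for EU and a time of 40 min, read here as RNA labelled with ethynyl uridine, a nucleoside taken up into newly made transcripts. The labels give no oxygen condition for the EU sample. Nothing in the labels says whether replicates came from separate cultures. A p-value of a test across libraries thus measures the spread between these libraries, which may be technical. Fisher tests and matched random lists run over genes, and their p-values hold no spread between libraries.

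The submitters' processing notes name STAR and the genome build hg38, with no version. The peak caller, its threshold, the use of the inputs and the gene annotation were not given in the sources used here. Each pulled-down library had its own peak list, and each of the 2 conditions had 1 more, whose making (pooled reads, joint calling or merging) is likewise not given in the sources used here. The lists had 12 BED columns without a header, with a gene name, a strand and the exon blocks of each peak. The deposited p-value of each peak was read from column 5, which ran from 0 to 0.013 in ascending order; the files do not name this column, so its meaning rests on its values. These values are the authors' and were used to describe and rank peaks within a list. Reads and input levels were not used here, so the depth of each library is unknown, and the lists say whether a peak was called, not how strongly a site was methylated or a gene expressed. A list holds peaks past a threshold only, and a gene without a peak is not thereby unmethylated or silent. Intervals cover counting error only.

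Starts were moved by 1 base to count from 1, as a genome browser does. Gene names were kept as in the lists. They were matched by name and by position, within 10 kb, to the RefSeq gene table of GRCh38.p14, for current symbols, gene types and gene spans, and 4595 of 5000 names (91.9%) matched. Without exon annotation or genome sequence, 2 planned results, the share of peaks by gene region and the share with the DRACH motif, were not run. Histone, ribosomal protein and other genes with near-identical copies were taken as the lists name them, and reads may have been split among the copies. How strand was used is not given in the sources used here, so overlapping genes on opposite strands are uncertain.

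Peaks were compared by strand and exon block, with a minimum overlap of 1 base. Covered bases were counted after merging. Peaks, covered bases and genes per library were compared on the log2 scale with an exact two-sided permutation test, which for 2 libraries against 2 has 6 assignments and cannot give a p below 0.333. Overlaps were set beside 100 random placements of each list inside the spans of the genes it lies in, introns included. They were given with exact binomial 95% intervals. A gene was called hypoxia-only when both hypoxia libraries had a peak in it and neither normoxia library did, and normoxia-only in the reverse case. Among genes with a peak in at least 1 of these 4 libraries, 19 gene lists were tested for hypoxia-only genes with Fisher's exact test, two-sided, and Benjamini-Hochberg adjustment over the 15 lists with at least 5 members there. The lists cover T cell receptor signalling and activation, T cell ligands and antigen presentation, HIF targets and HIF pathway, m6A writers, erasers and readers, neuroendocrine genes, chromatin regulators, stress responses, cell cycle, epithelial to mesenchymal transition, SR and hnRNP splicing factors, ribosomal proteins, mitochondrial mRNAs, ZNF genes, nuclear long non-coding RNAs, and markers of T and NK cells, of macrophages and of fibroblasts and endothelium. A further list counts in the tests and adjustments and is not described here, nor are some genes that the rule below names. The same lists were tested for a peak in both replicates of a condition against all RefSeq genes of the same types. Fisher tests treat genes as units, and genes are not replicates.

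Genes were named by a rule: up to 4 hypoxia-only and 2 normoxia-only genes of each list, up to 10 and 5 of all genes, 5 with a peak in all 4 libraries, 5 with a peak in the EU library and in none of the 4, each ranked by the smallest deposited p, and genes fixed for their topic, among them HIF1A, VEGFA, CA9, METTL3, METTL14, CD274, MALAT1 and MYC. The groups, tests, lists, rule and most alternatives were fixed before the data were examined. Alternatives kept the 50% of each list with the smallest p, kept peaks at least as wide as the median of 151 bases, kept chromosomes 1 to 22 and X, shortened each library to the 212 peaks of the smallest, left out each replicate, used every gene overlapped or protein-coding genes only, used the condition lists, or drew 10000 random lists matched on gene span and on the number of libraries with a peak. Gene span took the place of exon length in these draws, since exon lengths were not in the table. The list test was checked on simulated data with the real 3226 genes: with no effect, 0.2% of 3000 list tests passed in 200 simulations, and with the T cell receptor list weighted 4 times as likely to be called, 86.5% of simulations called it. With a weight of 2, 16% did. Apart from these weights the simulated calls were drawn evenly over genes. The check thus does not cover false calls in real data that arise from gene length or expression. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.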

Results

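Peak lists of 5 pulled-down libraries were compared: 2 of hypoxia, 2 of normoxia and 1 named for EU and 40 min, read here as labelled, newly made RNA, all from V16A prostate cancer cells. The study's title sets its question, whether m6A on nascent RNA takes part in a T cell activation signature that appears under hypoxia. Hypoxia replicates 1 and 2 had 2879 and 6621 peaks. Normoxia replicates 1 and 2 had 212 and 1563 peaks, and the EU library had 5044. Median peak width was 150 or 151 bases in the hypoxia and normoxia libraries and 199 in the EU library.

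The first comparison asked how many transcripts carried a called m6A peak in each condition. Genes with a peak numbered 1258 and 2151 in the hypoxia libraries and 139 and 897 in the normoxia libraries. MALAT1, a nuclear long non-coding RNA, had a peak in all 4, while HIF1A, the oxygen-regulated transcription factor, had 4 peaks in hypoxia replicate 2 and none in the other 3. On the log2 scale the mean was 10.68 ± 0.55 (SD, n = 2) in hypoxia and 8.46 ± 1.90 (SD, n = 2) in normoxia, a difference of 2.22, or 4.66-fold. Peaks differed by 2.92 on this scale, or 7.58-fold, and covered bases by 2.98. The exact permutation test gave p = 0.333 for each of the 3 measures, the smallest that 2 libraries against 2 allow, so none could pass a threshold of 0.05. The normoxia replicates differed 7.37-fold in peaks, and without normoxia replicate 1 the log2 differences fell to 1.48 in peaks, 1.504 in covered bases and 0.87 in genes.

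**Figure D1:**
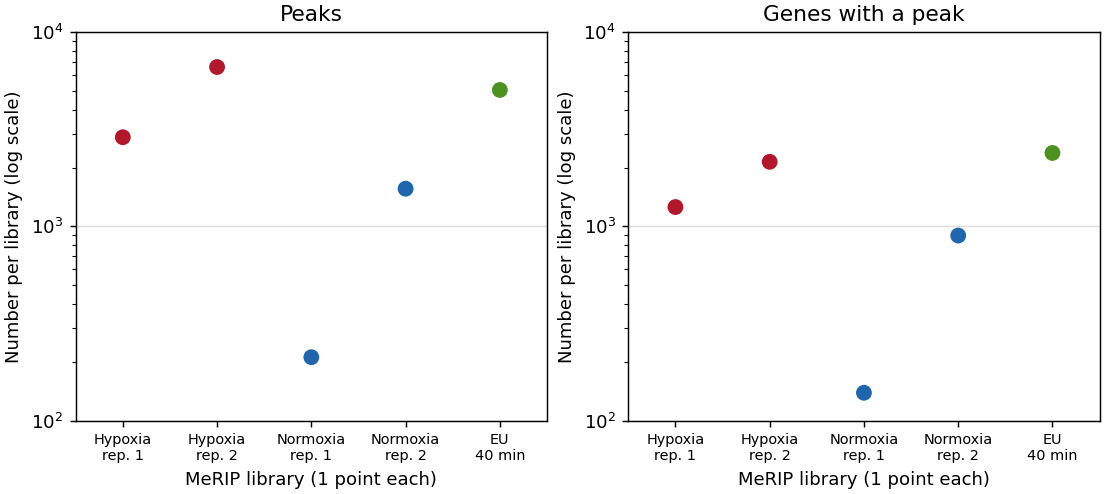
Number of peaks (left) and of genes with a peak (right) in each MeRIP library, 1 point per library on a log axis. Both hypoxia points, at 2879 and 6621 peaks, lie above both normoxia points, at 212 and 1563.

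The next question was which transcripts had a peak under hypoxia alone. There were 492 hypoxia-only and 5 normoxia-only genes among 3226 genes with a peak in at least 1 of the 4 libraries. By deposited p, the leading hypoxia-only genes were 4 replication-dependent histone genes, HIST1H2BL, HIST1H4C, HIST1H1D and HIST1H3I, then RAP2B, a small GTPase, CCL3, a chemokine, NCL, which encodes nucleolin, CBX5, which encodes heterochromatin protein HP1 alpha, WAPL, a cohesin release factor, and GPRIN3. HIST1H4C had 1 peak at chromosome 6, 26103972 to 26104117 (hg38), in both hypoxia libraries, with deposited p of 4.4e-06 and 3.2e-14. CBX5 had 8 and 13 peaks. Although neither normoxia library had a peak in them, the normoxia condition list had 1 each in CBX5, CCL3 and HIST1H1D and 2 in WAPL, and the hypoxia condition list had none in HIST1H1D. The normoxia-only genes were CEBPZ, TIMM13, MIS12, TSPYL1 and CTD-2541J13.2. The naming rule took only genes matched as protein-coding or long non-coding RNA. This left out the last of them, which was named after its values were seen. CEBPZ peaks lay at chromosome 2, 37228193 to 37228342, in normoxia replicate 1 and 37228242 to 37228391 in replicate 2. The hypoxia condition list had 3 peaks in CEBPZ and 2 in TSPYL1. Single genes were not tested: an exact test of presence in 2 libraries against 2 cannot give a p below 0.333. The counts moved with the library left out: hypoxia-only genes came to 1749 without hypoxia replicate 1 and 974 without hypoxia replicate 2, against 11 and 15 normoxia-only genes. Without normoxia replicate 1 there were 538 hypoxia-only and 469 normoxia-only genes, and without normoxia replicate 2 616 and 35. With the 50% of each list with the smallest p there were 173 and 1, and with every library shortened to 212 peaks 14 and 3. By the condition lists, 2077 genes had a peak in hypoxia and not in normoxia and 670 the reverse, but 699 of the 2637 genes of the hypoxia list and 527 of the 1230 of the normoxia list had no peak in either replicate.

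Genes of T cell receptor signalling were over-represented among the hypoxia-only genes. Of the 31 members with a peak, 14 were hypoxia-only (45.2%), against 15.3% of all 3226 genes (odds ratio 4.68, Fisher's exact adjusted p = 0.000995). Against random lists matched on gene span and number of libraries, which held a mean of 8.52, the ratio was 1.64 (adjusted p = 0.0270 by permutation of list membership among matched genes). The 14 included CD3D, CD3E and CD247, which encode chains of the T cell receptor complex, and JUN, a transcription factor of the AP-1 family that many cell types express. CD3E had 4 and 5 peaks in the hypoxia libraries, the best of replicate 2 at chromosome 11, 118312666 to 118312915, with a deposited p of 6.9e-07. CD247 had 1 and 6 peaks, and a peak of 2 exon blocks at chromosome 1, 167438601 to 167439493, was called in both. Markers of T and NK cell lineage moved with this list: of 14, 9 and 11 had a peak in the hypoxia libraries, 4 (CD2, GZMB, NKG7 and TRAC) in normoxia replicate 1, 0 in normoxia replicate 2 and 10 in the EU library. The lists share CD3D, CD3E, CD3G and CD8A, so they are not independent. CD3D and CD3E count as hypoxia-only in both. Among the 11 lineage markers with a peak in the 4 libraries, 5 were hypoxia-only (odds ratio 4.67, adjusted p = 0.0632 by Fisher's exact test). Without normoxia replicate 1 the odds ratio was 22.6. Since normoxia replicate 2 had none of the markers, each marker found in both hypoxia libraries was then hypoxia-only by construction. The lineage markers passed with the 50% of peaks with the smallest p (odds ratio 8.54, adjusted p = 0.0208) and with peaks at least as wide as the median (5.28, 0.0392), by Fisher's exact test. Their odds ratio was 0.996 without hypoxia replicate 1, 1.28 without hypoxia replicate 2 and 1.19 by the condition lists, and their adjusted p against matched random lists was 0.460. The receptor list lost its call with the condition lists (adjusted p = 0.244), with the 50% of peaks with the smallest p (0.654) and with leukocyte genes left out (0.102, with 6 of 16 genes, an odds ratio of 3.48 and an unadjusted p of 0.0219, chosen after seeing the data), all by Fisher's exact test. With each library shortened to 212 peaks none of its 5 members was hypoxia-only.

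**Figure D2:**
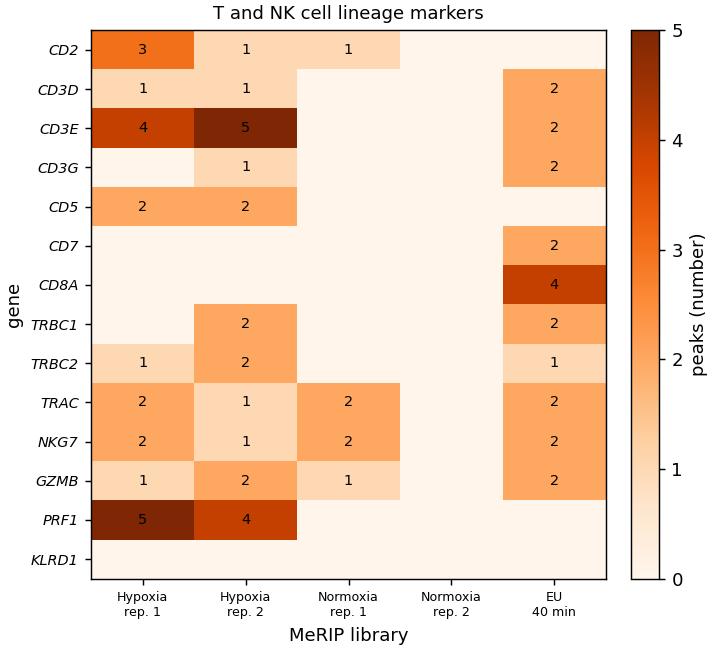
Number of peaks of each T and NK cell lineage marker (14 genes) in the 5 MeRIP libraries. Normoxia replicate 2 has no peak in any of them, and normoxia replicate 1 has peaks in 4, CD2, GZMB, NKG7 and TRAC.

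Splicing factors of the SR and hnRNP families were also over-represented, and ZNF genes under-represented, among hypoxia-only genes. Of 19 splicing factors with a peak, 9 were hypoxia-only (odds ratio 5.08, adjusted p = 0.00687 by Fisher's exact test). SRSF2 had 1 and 4 peaks, HNRNPD 3 and 5, HNRNPR 6 and 5, and SRSF7 3 and 2 in the hypoxia libraries. The best SRSF2 peak of hypoxia replicate 2 lay at chromosome 17, 76736241 to 76736538. Of 69 ZNF genes, which encode zinc finger proteins, 3 were hypoxia-only, ZNF195, ZNF777 and HKR1 (odds ratio 0.248, adjusted p = 0.0324 by Fisher's exact test). The lineage markers of T and NK cells had peaks in the same hypoxia libraries, as given above. The splicing factor call ended without hypoxia replicate 1 (adjusted p = 0.604) or 2 (0.255), and the ZNF call without hypoxia replicate 1 (0.128), hypoxia replicate 2 (0.261) or normoxia replicate 2 (0.143), by Fisher's exact test. Both calls also ended with the condition lists (0.244 and 0.253) and with the 50% of peaks with the smallest p (0.654 for both), and the ZNF call with leukocyte genes left out (0.0660), although the ZNF odds ratio hardly moved in the last 2 settings (0.259 and 0.257). Against random lists matched on gene span and number of libraries, the adjusted p was 0.416 for both.

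Antigen presentation, cell cycle and HIF target genes gave no call among hypoxia-only genes. Of 19 T cell ligand and antigen presentation genes, 6 were hypoxia-only (Fisher's exact adjusted p = 0.171), among them PSMB8, an immunoproteasome subunit, HLA-B, TAP1, a peptide transporter, and TGFB1. HLA-B had 3 peaks in the normoxia condition list. Without normoxia replicate 1 this list passed, with an odds ratio of 4.51 and an adjusted p of 0.00714. For cell cycle genes the count was 7 of 23 (Fisher's exact adjusted p = 0.178), with MCM4, CCND3, TYMS and KIF11, and the list passed without normoxia replicate 1 (adjusted p = 0.0224) and with peaks at least as wide as the median (9 of 21, odds ratio 3.99, adjusted p = 0.0118). For HIF targets it was 3 of 13 (Fisher's exact adjusted p = 0.812): PFKFB3, a glycolytic regulator, SLC2A3, a glucose transporter, and BHLHE40. Ribosomal protein genes counted 4 of 27 (among them RPL35, RPLP2 and RPS25), chromatin regulators 3 of 21 (DNMT1, NCOA2 and CHD4), and m6A factors 1 of 12 (HNRNPA2B1). Stress response genes counted 1 of 12 (SEL1L), HIF pathway genes 1 of 6 (TCEB2, now ELOB), and epithelial to mesenchymal transition genes 1 of 7 (TGFB1); each of these 6 lists had an adjusted p of 1. None of 7 nuclear long non-coding RNAs was hypoxia-only (Fisher's exact adjusted p = 1). Neuroendocrine, mitochondrial, macrophage, and fibroblast and endothelial lists had fewer than 5 members with a peak and were not tested. Ribosomal protein genes passed without hypoxia replicate 1 (adjusted p = 0.0490) and with the condition lists (0.000229), by the same Fisher test.

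**Figure D3:**
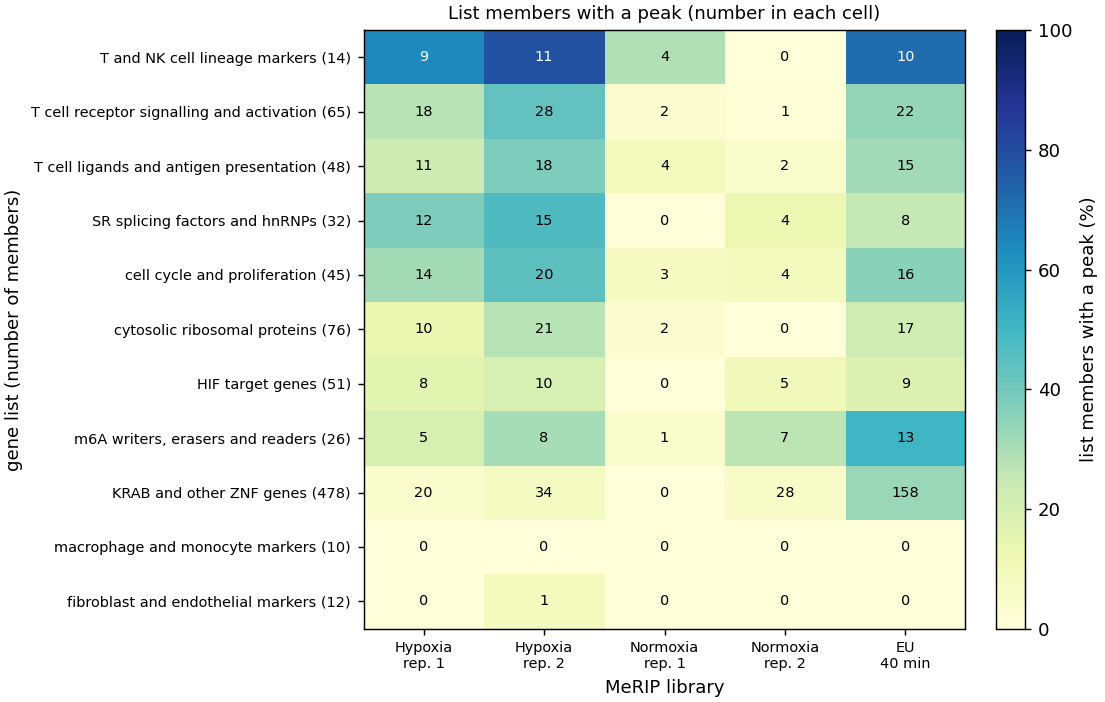
Share of the members of 11 gene lists with a peak in each MeRIP library, as colour, with the number of members in each cell and the list size in brackets. T and NK cell markers reach 11 of 14 in hypoxia replicate 2 and 0 in normoxia replicate 2.

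Set against all RefSeq genes of the same types, 5 lists had a peak in both hypoxia libraries more often than other genes. T and NK cell lineage markers led, with 9 of 14 (64.3%) against 3.14% of genes (Fisher's exact adjusted p = 1.75e-09). T cell receptor signalling had 15 of 65 (Fisher's exact adjusted p = 1.9e-08), cell cycle genes 12 of 45 (1.02e-07), splicing factors 10 of 32 (2.51e-07), and T cell ligands and antigen presentation 10 of 48 (1.3e-05). In normoxia, where 34 protein-coding genes had a peak in both libraries, no list passed Fisher's exact test after adjustment over 36 tests. At an unadjusted p under 0.05 there were 2, nuclear long non-coding RNAs (p = 0.0158) and m6A factors (p = 0.0432), with 1 member each by Fisher's exact test. By the condition lists, 10 lists passed the same test in hypoxia and 9 in normoxia, so the contrast between conditions was not kept. Whether the conditions differ in the shares of these lists was not tested. Gene expression, which also sets where a peak can be called, was not measured here.

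The overlap of peak lists was compared within and between conditions. FAM83H, H2AFX, a histone variant gene, HIST1H3H and HIST1H4I were among the leading genes of 20 with a peak in all 4 libraries. Of hypoxia replicate 1 peaks, 47.4% (exact 95% interval 45.6 to 49.3) were overlapped by a peak of replicate 2, against 10.3% for random placement in the same genes. Of normoxia replicate 1 peaks, 18.4% (13.4 to 24.3) were overlapped by normoxia replicate 2, 52.8% by hypoxia replicate 1 and 59.9% by hypoxia replicate 2, where random placement gave 4.75%, 17.8% and 19.7%. The Jaccard index of covered bases was 14.5% for the hypoxia replicates and 1.86% for the normoxia replicates, a mean of 8.17%, and averaged 3.36% between conditions (1.57% to 4.15%), so the hypoxia replicates alone carried the excess (exact permutation p = 0.333, the smallest that 3 labelings allow). Of normoxia condition peaks, 32.1% were overlapped by the hypoxia condition list, and 9.19% in reverse. These shares rise with the length of the other list. Random placement used whole gene spans, introns included, while the called peaks follow exon blocks. An excess over random placement thus does not by itself show shared sites. The Jaccard index depends on the lengths of both lists, and length was not taken out of the excess of the hypoxia replicates.

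The EU library, if it holds newly made RNA as read here, bears on which transcripts carry m6A peaks early. Of the 492 hypoxia-only genes, 214 (43.5%) had a peak in the EU library, near the 39.9% of all 3226 genes, among them CD3D, CD3E, CD247, PSMB8 and HNRNPR, while SRSF2, SLC2A3, MCM4 and CBX5 had none. A further 1101 genes had a peak in the EU library and in none of the 4. HNRNPA0, an RNA-binding protein gene, DUSP1 and PLK2, both immediate early genes, ATXN1L and COA7 led these, the last 2 with 2 peaks each in the hypoxia and the normoxia condition list, respectively. The best DUSP1 peak lay at chromosome 5, 172768582 to 172768976, with a deposited p of 1.1e-09. Of EU peaks, 34.3% (exact 95% interval 32.9 to 35.6) were overlapped by the hypoxia condition list and 18.6% (17.6 to 19.7) by the normoxia condition list. With the hypoxia list shortened to the length of the normoxia list, chosen after seeing the data, the first share was 10.2%, below the second. In reverse, 23.1% of hypoxia condition peaks and 45.6% of normoxia condition peaks were overlapped by EU peaks. There was 1 EU library, so these shares have no replicate check.

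Genes fixed for their topic were looked up in every library. VEGFA, the HIF target that drives vessel growth, had 2 peaks in each hypoxia library, 2 in normoxia replicate 2 and 4 in the EU library. Its best peaks overlapped near chromosome 6, 43784889 to 43785538 in hypoxia replicate 2 and 43785039 to 43785339 in normoxia replicate 2. MYC had 1 peak in normoxia replicate 2, 1 in the EU library and 1 in each condition list. CA9, METTL3, METTL14 and CD274 had no peak in any of the 7 lists. These differences were not tested.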

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

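Leaving out leukocyte genes and shortening the hypoxia condition list were chosen after seeing the data; the other alternatives were planned. Of 142 alternatives over 18 results, 6 reversed. Of 64 for the 5 gene list odds ratios, 38 kept direction and side of the threshold, 16 kept direction and lost the call, 4 gained it, and the 6 reversed include 2 more lost calls. The excess of peaks, covered bases and genes in hypoxia kept its direction in the 26 alternatives run, where no p could pass the threshold, with log2 differences without 1 replicate of 1.48 to 4.36, 1.504 to 4.45 and 0.87 to 3.56. With the replicate number as a block, the differences of 2.92, 2.98 and 2.22 stayed by construction, and the paired exact p was 0.5, the smallest that 2 pairs allow. The correlation between the replicates' differences was -0.0978 over 3226 genes.

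Hypoxia-only genes, 492, came to 173 with the 50% of each list with the smallest p, 14 with each library shortened to 212 peaks and 2077 by the condition lists, and to 538 to 1749 without 1 replicate (lowest without normoxia replicate 1, highest without hypoxia replicate 1). Fewer libraries to meet raise the count without 1 replicate by construction. In the other settings the cause was not tested. Lists past the threshold among them, 3, came to 1 with the smallest p, 5 with peaks at least as wide as the median, 0 with libraries shortened to 212 peaks, 1 by the condition lists, 1 without leukocyte genes, 1 against matched random lists, and 2 to 6 without 1 replicate (6 without normoxia replicate 1, 2 without each of the others). The cause was not tested.

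The odds ratio of T cell receptor signalling, 4.68, was 2.02 with the smallest p, 2.01 by the condition lists and 3.48 without leukocyte genes, in each case no longer past the threshold, and 2.91 to 8.29 without 1 replicate, past it each time (adjusted Fisher p from 0.000328 to 0.0312). With libraries shortened to 212 peaks it reversed to 0. The odds ratios of splicing factors, T and NK cell markers, and T cell ligands and antigen presentation did so too. In that setting 14 genes were hypoxia-only, 3.13% of those with a peak, so 0 was likely for any small list. The ligand list also reversed with the smallest p (0.831). Without 1 replicate, T and NK cell markers ranged from 0.996 (hypoxia replicate 1, a reversal) to 22.6 (normoxia replicate 1, the only normoxia library with peaks in them). The cause was not tested.

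Overlap fell when peaks had to share at least 50% of both: hypoxia replicate 1 in replicate 2 from 47.4% to 25.3%, normoxia replicate 1 in replicate 2 from 18.4% to 8.96%, normoxia in hypoxia condition list from 32.1% to 14.4%, and EU peaks in the hypoxia and normoxia lists from 34.3% to 15.7% and from 18.6% to 8.74%. With the smallest p the first 3 were 27.3%, 4.72% and 12.2%. By genes in place of peaks, the EU shares were 43.2% and 28.8%, and with the hypoxia list shortened the first was 10.2%. Only this cut and the stricter rule lower them by construction. Lists with a peak more often than other genes went from 5 to 10 in hypoxia and from 0 to 9 in normoxia by the condition lists; the cause was not tested. Not run, for want of exon annotation or sequence, were alternatives on exons, gene regions and motifs.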

Other observations

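All tests in this part were chosen after the results they measure were seen. ZNF genes, which encode zinc finger proteins, stood out among genes with a peak in the EU library and in none of the other 4: 111 of the 180 with a peak in the 5 libraries (61.7%), against 25.4% of 4327 genes (odds ratio 5.13, Fisher's exact adjusted p = 1.39e-24). None of the other 14 lists tested passed, with adjusted p of 0.648 or more. These tests rest on 1 EU library and were not matched on gene span. The condition lists were not counted, although they had a peak in 53 (hypoxia) and 37 (normoxia) of 478 ZNF genes. HIST genes, which encode histones, were counted because they led the hypoxia-only ranking: 19 of 38 were hypoxia-only, and 30 and 34 had a peak in the hypoxia libraries, 9 in normoxia replicate 1, 3 in normoxia replicate 2 and 13 in the EU library. Among the 139 genes of normoxia replicate 1, 9 is a larger share than 30 of 1258 or 34 of 2151 in hypoxia. Their near-identical copies leave single members uncertain.

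Genes of cytotoxic and other leukocytes, among them GNLY, GZMA, IL2RB, KLRK1, PTPRC and CORO1A, had peaks beside the T and NK cell markers. Of 18 such genes, 15 and 16 had a peak in the hypoxia libraries, 5 in normoxia replicate 1, 0 in normoxia replicate 2 and 13 in the EU library. Of the 16 with a peak in the hypoxia or normoxia libraries, 10 were hypoxia-only (odds ratio 9.43, Fisher's exact adjusted p = 8.4e-05). The list was not among those fixed before the data were examined, and its members may have been chosen with their peaks in view. Its p-value thus cannot be read as an independent test. When the T cell receptor list was parted, genes restricted to T cells counted 8 of 15 (odds ratio 6.44, adjusted p = 0.00132) and widely expressed ones 6 of 16 (odds ratio 3.36, adjusted p = 0.0334, both by Fisher's exact test over 4 lists). The 16 widely expressed genes are those left when leukocyte genes are left out, where over 14 lists the adjusted p was 0.102, so this pass rests on the number of lists. Of 7 epithelial genes none was hypoxia-only (Fisher's exact adjusted p = 0.604), and of 10 B cell markers 1 had a peak, in hypoxia replicate 2. Peaks on the minus strand made up 63.0% to 75.9% of each of the 5 libraries. Peaks of more than 1 exon block made up 35.9% and 36.7% in hypoxia, 29.7% and 9.92% in normoxia and 19.8% in the EU library.

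T and NK cell markers had a peak in 4 of 5 libraries and in none of normoxia replicate 2. A random loss of genes does not account for this: a random draw of 897 genes from a larger library would hold no marker with a probability of at most 0.00892. A shorter list need not lose genes at random, so the size of the library is not excluded. RNA of T or NK cells is a candidate explanation that the tables do not decide: the markers had a peak more often than 22 macrophage, fibroblast and endothelial markers in each of the 4 libraries (highest Fisher's exact p = 0.0170), but those had at most 1, so the test restates the pattern. Normoxia replicate 1 held a larger share of markers than normoxia replicate 2 (2.88% against 0% of genes, Fisher's exact p = 0.000312). That test sets 1 library against 1 over genes and restates the 0 that prompted it. The share was also larger than in the hypoxia libraries (0.715% and 0.511%, in longer lists). Epithelial genes had a peak in 2 and 3 of 16 in hypoxia, 2 and 5 in normoxia and 6 in the EU library. With 1 such normoxia library, an effect of hypoxia on the cancer cells and a source outside them cannot be told apart, and markers of the line's own lineage are not described here.

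The larger number of peaks in hypoxia, of which MCM4, CBX5 and HNRNPR are examples, may reflect depth or pull-down yield. The normoxia replicates, under 1 label, differed 7.37-fold, near the 7.58-fold between conditions, and read depth was not used here, so yield and an effect of hypoxia cannot be told apart. With the small list of normoxia replicate 1 set aside, the nearest hypoxia library had 1.84 times the peaks of normoxia replicate 2, against 2.30 between the hypoxia libraries, which leaves that list's part open too.

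Normoxia replicate 1, with peaks in GZMB, NKG7 and TRAC, overlapped the hypoxia and EU lists more than normoxia replicate 2. The length of those lists may account for it: with lists of equal gene numbers they held 39.6%, 33.1% and 28.8% of its genes, near the 29.5% (exact 95% interval 22.1 to 37.8) in normoxia replicate 2, although hypoxia replicate 1 lay above that interval. A swap with a hypoxia library is not decided. The hypoxia libraries resembled each other (Jaccard 14.5%) more than either did normoxia replicate 2 (at most 4.15%), but this index depends on list length. Relative to random placement, which took in introns and is no measure of shared sites, the order was not kept. Of hypoxia replicate 1 peaks, 47.4% were overlapped by hypoxia replicate 2, against 10.3% at random. Of normoxia replicate 2 peaks, 14.3% and 28.0% were overlapped by hypoxia replicates 1 and 2, against 2.82% and 5.59%. Without leukocyte genes, at least 51.2% of the genes of normoxia replicate 1 were in a hypoxia library and 31.8% in normoxia replicate 2. These lists are of unequal length, so a wrong label or RNA of another sample cannot be told apart from this.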
